A study of Salmo salar with 120 samples.

How the data were processed

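Liver RNA from juvenile Atlantic salmon was measured on 120 arrays, 6 for each of the 20 combinations of 10 diets and 2 sampling days, 14 d and 56 d. Per the labels, only RNA with a quality indicator above 8 was used, and 200 ng of each sample was amplified and labelled with Cy3. Each array carried 1 sample and 43689 probes besides its control spots. The labels do not say whether the 6 replicates of a group are separate fish, pools or tanks, so every p-value here measures only the spread between these arrays.

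Per the file headers, the scanner files hold linear spot intensity from Agilent Feature Extraction 10.7.3.1 under its 1-colour gene expression protocol, background-subtracted and spatially detrended, with no scaling between arrays. The authors' table holds log2 values, and comparison with the scanner files spot by spot showed that each of its columns is the log2 of the processed signal plus 1 constant per array, blank where the scanner file marks the spot. Between 9675 and 27554 spots per array were blank for that reason. The scanner files were used throughout, and the authors' log2 table served as an alternative.

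Depth was read as signal over background. Between 16618 and 34411 probes per array were well above background by Feature Extraction's own call, which is 38.0% to 78.8% of the probes. The 75th percentile of the processed signal lay between 75.6 and 588 intensity units, and at most 1 probe was saturated on any array. The number of arrays limits the precision.

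Control spots were left out, and spots marked as outliers by Feature Extraction were treated as missing, 0.0526% of the values tested. The log2 of the processed signal was taken, and each array's 75th percentile on that scale was subtracted, so that all log2 values are relative to that level. Probes well above background on at least 6 of the 120 arrays were kept, 36225 in all. A linear model with 1 mean per group was fitted in limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with the data.table package, version 1.17.8, with 100 residual degrees of freedom shared by all groups. Moderated contrasts gave each supplemented diet against the control diet of the same day, 3 planned contrasts between related by-products at each day, the change from 14 d to 56 d, and the difference of each diet effect between the days. Moderated F tests covered the 9 diet contrasts of a day and the 9 differences between days. A probe passed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The p-values of contrasts are two-sided, adjusted p-values in the text are limma's, and errors of log2 changes are its standard errors (SE). A change is stated as "at least" so many fold where the probe was well above background on no array of one group, with the dim values raised to the array's background limit. No such bound was set for differences between the days, where 4 groups enter. The groups, comparisons, tests and the first set of other settings listed below were chosen before the data were examined.

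The probes carry no gene names. Of their labels 23278 give a clone position, 19956 a sequence cluster, 409 a sequence accession and 46 something else, and 0 of the 409 accessions were found in the reference table of 65341 salmon genes. The 31 gene lists fixed beforehand therefore had 0 members that could be named, and they were not analysed here. Probes are identified by their position on the array, and their genomic location and function are unknown here. For each comparison the text names up to 2 probes with the largest rise and 2 with the largest fall among those that passed, and for each F test the 2 probes with the smallest adjusted p. Other probes are named only where so stated.

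The pipeline was tested on simulated data with 200 changed probes in the arrangement of the herring tails comparison at 14 d. It recovered 2%, 36%, 80% and 96% of changes of 0.5, 1, 2 and 3 on the log2 scale, and 12 of its 119 calls were outside the changed probes. The other 17 diet comparisons of the simulated data gave 1 call. The simulated values varied independently between arrays and between probes, without the likeness of real arrays on the same slide. These rates therefore hold only for data without such structure.

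Scan days were taken from the headers of the scanner files and slides from their names, which gave 31 slides of up to 4 arrays and 8 scan days. Other settings fixed beforehand were quantile normalization, the normexp background correction with an offset of 50 applied to the median spot signal and the local background, the authors' log2 table, no filter on dim probes, slide as a fixed and as a random block, the replicate number as a block, a model with only the arrays compared, and leaving out each replicate number in turn. Added after seeing the data were leaving out the 2 arrays that were unlike all others (also combined with a model of only the arrays compared), scan day as a block, array brightness as a covariate, leaving out the 3 arrays with the fewest probes above background, and leaving out single arrays. Normexp was planned on the mean spot signal, which was not used here. Within each slide and scan day that held both groups, the direction of 100 probes was followed that had the smallest p on all arrays outside it, so that no probe was chosen on the arrays compared. Such probes are not independent of each other, and this test was added after seeing the data. For each comparison the arrays were also regrouped at random, with 100 splits that included the real one, and for herring tails at 14 d also with slide as a block or array brightness in each fit, chosen after seeing the data.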

Results

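The series asked how the liver of juvenile Atlantic salmon responds to feed supplemented with marine by-products. Liver RNA was measured on 120 arrays after 14 d or 56 d on a control diet or on 1 of 9 supplemented diets, with 6 arrays in each of the 20 groups. The by-products were crab hepatopancreas, herring tails, shrimp fine meat, herring milt (the sperm-bearing testis), sea cucumber, herring roe (the eggs), a hydrolysate of herring milt and 2 hydrolysates of shrimp, labelled B and C. A hydrolysate is a by-product whose protein has been broken into shorter peptides. Between 16618 and 34411 of the 43689 probes were well above background on each array, and 36225 probes were tested. Log2 values are given relative to each array's 75th percentile. The probes could not be linked to gene names, so they are identified by their position on the array.

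Of the 120 arrays, 2 differed from all others. Replicate 2 of crab hepatopancreas at 14 d and replicate 2 of herring tails at 14 d correlated across probes with the median array at r = 0.675 and r = 0.703, while the other 118 lay between 0.919 and 0.988. Of the 200 brightest probes, 71 were more than 16-fold lower than the median array on both of these arrays, and at most 2 were so on any other array. Both were kept in the tests as labelled, and the results below are also given without them where that moved a count by more than 1.5-fold.

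**Figure D1:**
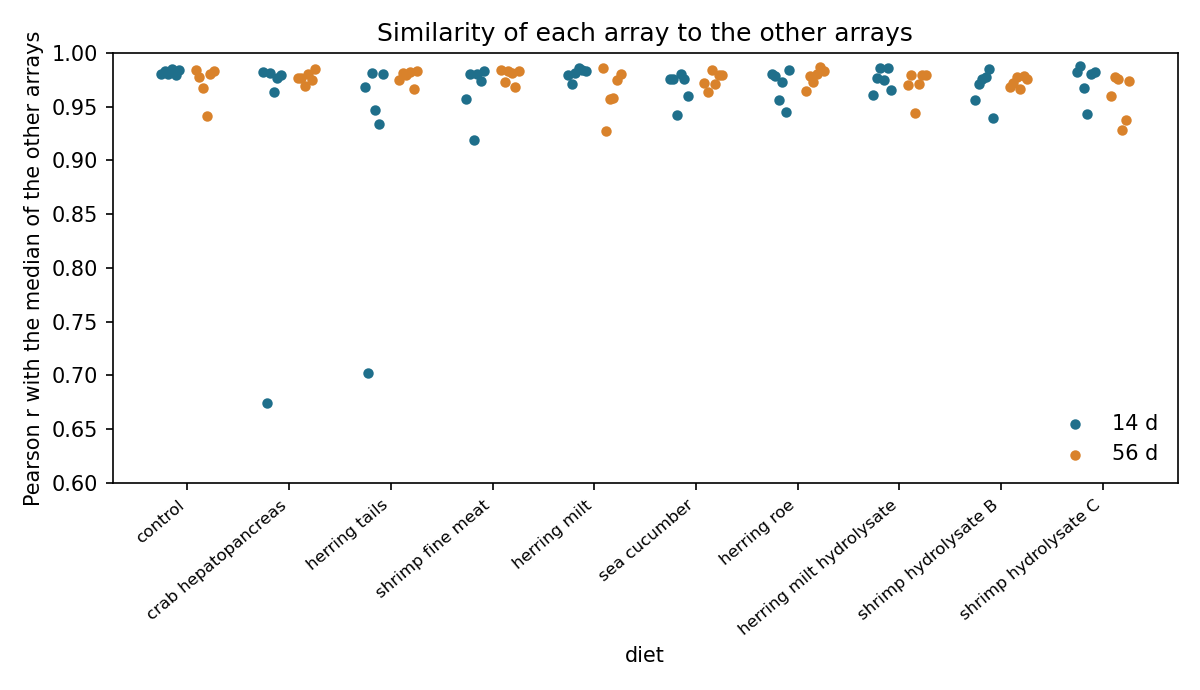
Pearson correlation across probes of each of the 120 arrays with the median array (vertical axis), by diet and day (horizontal axis), 1 point per array. Replicate 2 of crab hepatopancreas and of herring tails at 14 d lie at 0.675 and 0.703, and all other arrays lie at 0.919 or above.

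At 14 d the diets differed at 2009 probes by limma's F test over the 9 diets, a count that 7 of 100 random splits of the arrays reached, the real one included, with 3877 in the highest other. The smallest adjusted p values belonged to C061R119 and C195R052, both 5.55e-10, and both probes were lowest after herring tails. C061R119 measured 5.93 ± 0.75 (SD, n = 6) after herring tails and 7.52 ± 0.26 (SD, n = 6) on the control diet. C195R052 measured 5.65 ± 0.70 and 7.17 ± 0.22 in the same groups. In single diets, 1432 probes changed against control at 14 d, in 3 of the 9 diets, and 49 of them did so in more than 1 diet. The F test called 2629 probes without the 2 unlike arrays, where only the real split reached that count, while normexp background correction left 445 and a model of the 14 d arrays alone left 989.

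**Figure D2:**
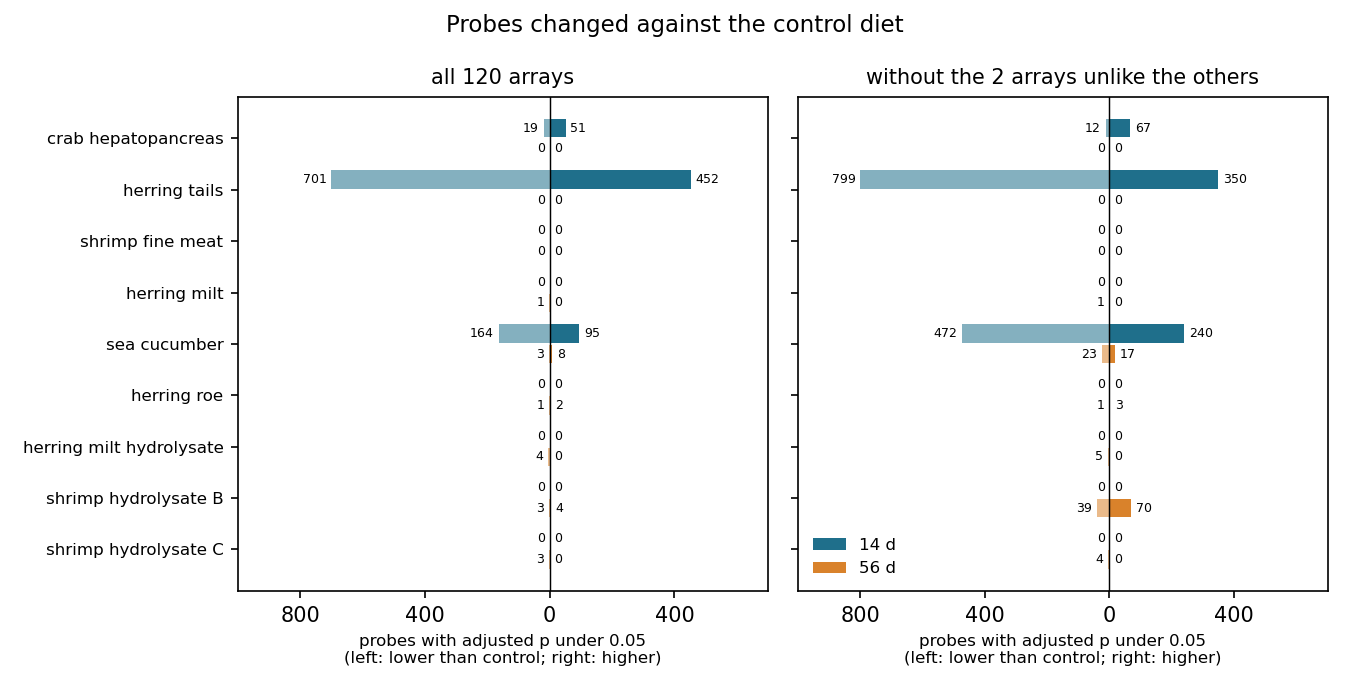
Number of probes that rose (up) or fell (down) against the control diet of the same day at an adjusted p under 0.05 (horizontal axis). Each of the 9 supplemented diets is shown at 14 d and 56 d, with all arrays (6 per group) and without the 2 unlike arrays. With all arrays herring tails at 14 d gave 452 rises and 701 falls, and no diet exceeded 11 changed probes at 56 d. Without the 2 unlike arrays herring tails at 14 d gave 350 rises and 799 falls. At 56 d shrimp hydrolysate B then had 109 changed probes and sea cucumber 40.

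With all arrays in 1 model, herring tails had the most called probes of the 9 diets at 14 d. Against the control diet 452 probes rose and 701 fell, 1153 in all or 3.18% of those tested, and 842 of them changed more than 2-fold. C195R030 rose 18.9-fold, from 0.84 ± 1.90 (SD, n = 6) on the control diet to 5.08 ± 1.38 (SD, n = 6), and C127R076 rose 11.6-fold. C067R165 fell 10.5-fold and C228R017 fell 9.79-fold. The log2 changes of the rising pair were 4.24 ± 0.78 (SE, adjusted p = 0.000167) and 3.53 ± 0.73 (SE, adjusted p = 0.00089), with 5 of 6 arrays above every control array for each. Those of the falling pair were -3.39 ± 0.84 (SE, adjusted p = 0.00845) and -3.29 ± 0.87 (SE, adjusted p = 0.0166), with 5 and 6 of 6 arrays below every control array. Without the 2 unlike arrays C067R165 fell 5.26-fold and C228R017 fell 3.18-fold, and 1149 probes passed, 350 up and 799 down, of which 756 were among the original calls. Of the 100 probes with the smallest p on the arrays outside it, 99% had the same direction within the 1 slide that held both groups, and likewise 88% to 98% within each of 4 scan days, with 1 or 2 arrays of a group in each. With slide as a fixed block 599 probes passed and the original calls kept a median of 0.81 of their log2 size, and with normexp 166 passed (99 up and 67 down) at 0.586. In a model of only the 2 groups 5 passed for herring tails, or 541 without the unlike array, and in such a model sea cucumber had 513. The count was 751 without control replicate 5, 1944 without herring tails replicate 6 and 2306 without herring tails replicate 3.

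At 56 d no probe passed for herring tails against control by limma, with 1709 at an unadjusted p under 0.05. The probes that had risen at 14 d had a median log2 difference of 0.08 at 56 d, and those that had fallen had one of 0.16. The difference between the days itself passed at 343 probes, with 223 moving up and 120 moving down relative to the control diet between 14 d and 56 d. C013R095 moved up by 3.01 ± 0.61 on the log2 scale (SE, adjusted p = 0.00524). It measured 1.92 ± 1.73 after herring tails and 4.48 ± 0.58 on the control diet at 14 d, and 4.09 ± 0.50 and 3.64 ± 0.40 at 56 d (SD, n = 6 each). C093R164 moved up by 2.79 ± 0.75 (SE, adjusted p = 0.0423). C080R059 and C155R007 moved down (adjusted p = 0.0205 and 0.0254), but each was well above background on no array of 1 of the 4 groups and on at most 4 of 6 arrays of the others, so the size of their change was not measured. With the 2 unlike arrays left out 1090 probes passed and the change of C013R095 was 2.32, while 32 probes passed with slide as a fixed block (the original calls at a median of 0.656 of their size), 143 with slide as a random block, 0 with normexp (at 0.56, with 84% in the same direction) and 165 without the 3 arrays with the fewest probes above background. A model of only the 4 groups gave 0, or 1287 without the unlike array, and leaving out 1 replicate number gave 23 (control replicate 3, at both days) to 720 (replicate 2 of the supplemented diets).

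C067R165 was lower with sea cucumber than on the control diet at both days. The probe measured 0.67 ± 1.55 against 5.52 ± 0.77 on the control diet at 14 d (SD, n = 6), a fall of 28.7-fold, and at 56 d it fell 40.5-fold from 5.34 ± 0.97 (SD, n = 6). It was the 1 probe called for the same diet at both days, and its call held in each of the 24 alternatives tried at either day, which most other named calls did not. At 14 d C201R032 also fell 26.8-fold, while C137R052 rose 12.04-fold and C065R100 rose 8.11-fold. At 56 d C229R065 rose 7.24-fold and C248R020 rose 6.83-fold, while C262R013 fell 9.13-fold.

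In all, 95 probes rose and 164 fell at 14 d with sea cucumber, and 8 rose and 3 fell at 56 d. The log2 change of C067R165 was -4.84 ± 0.84 at 14 d (SE, adjusted p = 0.00139) and -5.34 ± 0.84 at 56 d (SE, adjusted p = 0.00013), with 6 of 6 arrays below every control array at both days. Those of C201R032, C137R052 and C065R100 at 14 d were -4.74 ± 0.92, 3.59 ± 0.85 and 3.02 ± 0.61 (SE), with adjusted p of 0.00415, 0.0191 and 0.00613. C229R065, C248R020 and C262R013 changed by 2.86 ± 0.45, 2.77 ± 0.51 and -3.19 ± 0.67 at 56 d (SE), with adjusted p of 0.00013, 0.00494 and 0.0264, and in each of these 6 calls 6 of 6 arrays lay beyond every control array. Of the probes that fell with sea cucumber at 14 d, 27 also fell with herring tails, where 3.17 would if the lists were independent, and 1 rose with both, where 1.19 would. Both lists were set against the same 6 control arrays, which can add shared calls. Simulated groups without effects of single diets, set against these controls, shared at most 0 falls and 0 rises. This argues against the controls alone as the source of the 27, but such groups lack the diet effects that the controls could add to. With those controls split between the comparisons no probe was called in both, but only a median of 3.5 passed for sea cucumber then. A part played by the shared controls was therefore not excluded. No slide held both groups at either day, and within scan days 70% to 94% of 100 probes chosen in the same way on the other arrays had the same direction at 14 d and 69% to 70% at 56 d. The difference between the days passed at no probe by limma for sea cucumber, with 2450 at an unadjusted p under 0.05, and at 9 with the authors' values. Without the 2 unlike arrays 712 probes passed at 14 d and 40 at 56 d, the latter 17 up and 23 down. In the fit with slide as a fixed block 67 passed at 14 d (47 up and 20 down), 45 of them original calls. At 56 d 3 passed in that fit, 1 of them an original call. The original calls were at a median of 0.89 and 0.882 of their size. Normexp left 9 at 14 d (at 0.6, with 89.2% in the same direction), and the authors' values gave 280 at 14 d, 146 up and 134 down. At 14 d the count was 102, 116, 123 and 161 without control replicate 2, 5, 1 and 4, and 122, 135 and 157 without sea cucumber replicate 6, 3 and 2. At 56 d it was 3, 3 and 6 without control replicate 1, 6 and 5, and 2, 2, 3, 3 and 20 without sea cucumber replicate 4, 6, 2, 5 and 3.

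**Figure D3:**
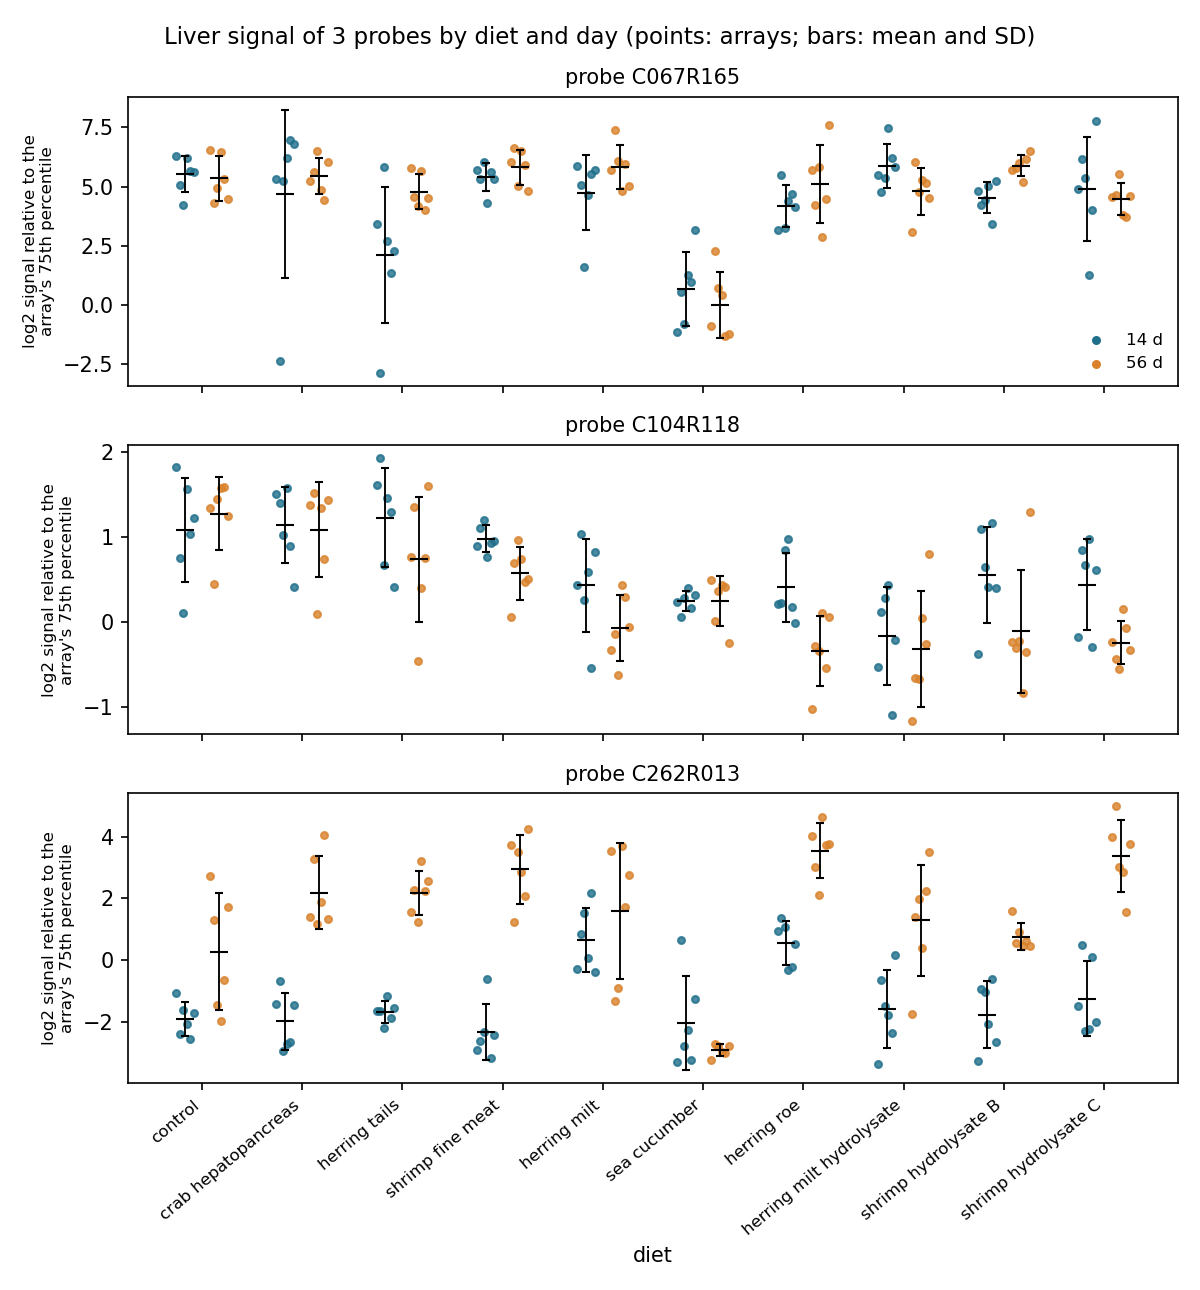
Log2 value relative to the array's 75th percentile (vertical axis) of the 3 probes named in the most comparisons, C067R165, C104R118 and C262R013, in each diet and day, 1 point per array, with the mean and SD of 6 arrays. C067R165 after sea cucumber averages 0.67 at 14 d against 5.52 on the control diet.

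With crab hepatopancreas 51 probes rose and 19 fell against the control diet at 14 d. C043R091 rose 13.7-fold and C024R016, well above background on no control array, rose at least 3.23-fold. C027R095 fell 16.04-fold and C105R095 fell 14.0-fold. Their log2 changes were 3.77 ± 0.84, 2.74 ± 0.55, -4.004 ± 0.86 and -3.81 ± 0.86 (SE), with adjusted p of 0.0254, 0.016, 0.0215 and 0.0285, and for each probe 6 of 6 arrays lay beyond every control array. Replicate 2, 1 of the 2 unlike arrays, set much of these values. Without the pair, C043R091 rose 7.00-fold and its adjusted p of 0.0701 no longer passed (0.00953 to 0.219 over all alternatives), C027R095 fell 5.34-fold and C105R095 fell 4.42-fold. The count was then 79, 67 up and 12 down, with 46 of the original calls among them. Both groups shared 2 slides and 4 scan days, within which 78% to 92.9% and 60% to 97% of 100 probes chosen on the other arrays had the same direction. In the fit with slide as a fixed block 10 probes passed, 7 of them original calls. The original calls were all in the same direction there, at a median of 0.907 of their size. Normexp gave 66 probes, 25 of them original calls. A model of only the 2 groups left 0, or 115 without the unlike array. The count was 2, 14, 18 and 28 without control replicate 6, 5, 1 and 4, and 6, 21 and 287 without crab hepatopancreas replicate 4, 5 and 6. At 56 d no probe passed by limma, with 1017 at an unadjusted p under 0.05.

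The other six diets changed no probe at 14 d by limma. At an unadjusted p under 0.05 there were 2853 probes for shrimp fine meat, 721 for herring milt, 997 for herring roe, 716 for herring milt hydrolysate, 1057 for shrimp hydrolysate B and 1002 for shrimp hydrolysate C. Each 14 d comparison had a median SE near 0.36 on the log2 scale. In simulated data with independent arrays 36% of changes of 1 on that scale were recovered, so most responses of this size or smaller may have been missed.

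At 56 d the diets differed at 545 probes by the F test, led by C262R013 (adjusted p = 1.19e-11) and C077R155 (adjusted p = 3.69e-08). C262R013 measured 3.55 ± 0.88 after herring roe and 3.36 ± 1.16 after shrimp hydrolysate C, against 0.28 ± 1.90 on the control diet and -2.91 ± 0.19 after sea cucumber (SD, n = 6 each). C077R155 was highest after sea cucumber, at 2.67 ± 0.42 against 1.02 ± 0.45 on the control diet (SD, n = 6). Only 23 probes changed against control in any single diet at this day, 4 of them in more than 1 diet. The F test called 1815 probes without the 2 unlike arrays, with slide as a fixed block 109 and with normexp 66.

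C104R118 fell in 4 diets at 56 d, all set against the same 6 control arrays. It fell 3.07-fold with herring roe, 3.02-fold with herring milt hydrolysate, 2.62-fold with shrimp hydrolysate B and 2.87-fold with shrimp hydrolysate C (log2 changes of -1.62, -1.60, -1.39 and -1.52, each ± 0.29 SE, with adjusted p of 0.00613, 0.00835, 0.0305 and 0.0133). C123R101 fell 3.66-fold with herring milt, as the single call of that diet, and 4.02-fold with shrimp hydrolysate C (-1.87 ± 0.35 and -2.01 ± 0.35 SE, adjusted p = 0.0147 and 0.00266). C091R025 fell 3.07-fold with herring milt hydrolysate and 3.22-fold with shrimp hydrolysate C (-1.62 ± 0.34 and -1.69 ± 0.34 SE, adjusted p = 0.048 and 0.0269). C104R118 in shrimp hydrolysate C and the other two falls with herring milt hydrolysate, C120R046 by 2.66-fold and C205R044 by 2.69-fold (adjusted p = 0.0243 for each), were named after their values were seen.

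C262R013 rose 9.61-fold with herring roe at 56 d, and C007R057 rose at least 3.81-fold. Their log2 changes were 3.27 ± 0.67 and 2.97 ± 0.59 (SE, adjusted p = 0.0432 and 0.0325), and C007R057 was well above background on 3 roe arrays and on no control array. C070R049 rose 3.80-fold and C095R031 3.03-fold with shrimp hydrolysate B, and C140R147 fell 1.70-fold (1.93 ± 0.38, 1.60 ± 0.32 and -0.76 ± 0.16 SE, adjusted p = 0.0137, 0.0204 and 0.0325). The counts were 3 for herring roe, 4 for herring milt hydrolysate, 7 for shrimp hydrolysate B, 3 for shrimp hydrolysate C and 1 for herring milt. Chance was not excluded for shrimp hydrolysate C, whose count 9 of 100 random splits reached, or for herring milt, where 15 did. With normexp 1 probe passed for herring roe, 1 for herring milt hydrolysate and 0 for each of the other three. Without control replicate 5 herring roe had 0, without control replicate 4 herring milt hydrolysate had 0, and in a model of only the arrays compared herring roe had 0, herring milt 0, herring milt hydrolysate 2 and shrimp hydrolysate C 1. Shrimp fine meat changed no probe by limma, with 1028 at an unadjusted p under 0.05. For shrimp hydrolysate B 109 probes passed without the 2 unlike arrays and 132 in a model of only the arrays compared. With slide as a fixed block the counts were 0 for herring roe, 0 for herring milt hydrolysate, 2 for shrimp hydrolysate B, 1 for shrimp hydrolysate C and 3 for herring milt, while C104R118 was at -1.56 with herring roe and -1.69 with herring milt hydrolysate (adjusted p = 0.234 and 0.272).

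Hydrolysed herring milt differed from whole milt at 56 d at 34 probes, of which 12 were higher and 22 lower with the hydrolysate. C125R093 was 6.59-fold and C212R023 6.25-fold higher, while C030R114 was 8.08-fold and C117R159 at least 2.20-fold lower. Their log2 differences were 2.72 ± 0.51, 2.64 ± 0.58, -3.01 ± 0.70 and -1.99 ± 0.43 (SE), with adjusted p of 0.00757, 0.0268, 0.0455 and 0.0204. For C125R093 4 of 6 hydrolysate arrays lay beyond every milt array, and for the other three 6 of 6 did. At 14 d no probe passed by limma, with 1232 at an unadjusted p under 0.05. No slide held both groups, and within 4 scan days 76% to 88% of 100 probes chosen on the other arrays had the same direction. Leaving out the 2 unlike arrays gave 230 probes (61 up and 169 down), with the authors' values 65 (9 up and 56 down), and with quantile normalization 59 (11 up and 48 down). With slide as a fixed block 0 passed, although the original calls kept a median of 0.885 of their size, and with normexp 0 passed and they kept 0.394. The count was 3, 4, 130, 153, 177 and 208 without milt replicate 2, 3, 4, 6, 1 and 5, and 12 and 19 without hydrolysate replicate 5 and 4.

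The shrimp hydrolysates C and B did not differ at any probe by limma, with 954 probes at 14 d and 1634 at 56 d at an unadjusted p under 0.05. At 56 d 10 probes passed without the 2 unlike arrays and 3 with the authors' values. Their mean differed from shrimp fine meat at C102R161 and C199R155 at 56 d, which were 1.75-fold and 1.56-fold lower with the hydrolysates (-0.81 ± 0.16 and -0.64 ± 0.12 SE, adjusted p = 0.0217 for each). Of the 12 hydrolysate arrays, 11 lay below every fine meat array for C102R161 and 9 for C199R155. At 14 d no probe passed by limma, with 1418 at an unadjusted p under 0.05. Chance was not excluded for these 2 probes, since 7 of 100 random splits gave as many. At 56 d 0 probes passed with slide as a fixed block (C102R161 at -0.50 and C199R155 at -0.51) or random block, scan day, array brightness, normexp, the authors' values or only the arrays compared, while 5 passed with quantile normalization and 9 without the 2 unlike arrays.

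From 14 d to 56 d, averaged over the 10 diets, 1676 probes rose and 1822 fell. C262R013 rose 7.21-fold, from -1.33 ± 1.38 to 1.52 ± 2.18 (SD, n = 60 each), and C112R144 rose 2.43-fold. C016R147 fell 4.26-fold and C195R081 fell 2.90-fold. Their log2 changes were 2.85 ± 0.21, 1.28 ± 0.19, -2.09 ± 0.26 and -1.54 ± 0.20 (SE), with adjusted p of 4.61e-20, 2.80e-07, 3.88e-09 and 8.64e-09, and 26, 16, 1 and 7 of the 60 later arrays lay beyond every earlier array. Most of the 3498 changes were small, with a median size of 0.34 on the log2 scale, and 52 exceeded 2-fold. Among the 3301 called probes with no missing value, sea cucumber had the same direction as the mean of the other nine diets at 62.1%, herring milt hydrolysate at 76.8% and the other eight at 82.5% to 96.6%, although the probes were called on the mean over these same diets. Over all probes, which are not independent replicates, the change of a diet correlated with that mean at r = -0.0416 for sea cucumber to r = 0.39 for shrimp fine meat. Of 100 probes chosen on the other arrays, 32% to 100% had the same direction within each of 25 slides that held both days, with a median of 93% and more than 50% in 23 of the slides, and 92% to 100% within each of 8 scan days. With slide as a fixed block 3798 probes passed, of which 2418 were among the 3498 original calls. Normexp gave 1321, of which 1264 were among them. There the original calls were at a median of 0.653 of their size and 91.1% of them kept their direction. On the control diet alone no probe passed by limma, with 2781 at an unadjusted p under 0.05, and 5 passed without the 2 unlike arrays.

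The effect of diet differed between the days at 127 probes by the F test over the 9 diets. C172R046 and C262R013 led, both with an adjusted p of 4.88e-04. C172R046 measured -0.66 ± 0.98 after herring tails and -3.47 ± 0.85 on the control diet at 14 d, and -2.93 ± 0.92 and -3.70 ± 0.46 at 56 d (SD, n = 6 each). C262R013 was 0.56 ± 0.70 after herring roe, -2.03 ± 1.52 after sea cucumber and -1.90 ± 0.54 on the control diet at 14 d (SD, n = 6 each). Of the single diets, herring tails alone had probes past the threshold, and the other eight had 0 by limma, with 533 to 2883 probes at an unadjusted p under 0.05. The F test called 474 probes without the 2 unlike arrays and 21 with normexp.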

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

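The tests of whether a diet effect differed between the days were planned, and every test of an explanation in this part was chosen after the result was seen. Single values are given where the gap between 1 array and its nearest companion took up most of its group's range. Chance marks about 1 group in 20 in this way, and 14 of 80 groups of named probes and 6 of 40 groups of array measures were marked.

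In crab hepatopancreas and herring tails at 14 d, replicate 2 correlated with the median array at r = 0.675 and r = 0.703 across probes, while the other arrays of these groups lay between 0.964 and 0.983 and between 0.934 and 0.981. The tables argue against a misplaced grid, because the signals of 10 spike-in probes followed the median ladder at r = 0.9988 or more, against a lowest value of 0.9855 on the other 118 arrays, and against weak or degraded RNA, because at least 29876 probes were well above background, more than the median of 29110 on the other arrays, and against the diets, since the other 10 arrays of the 2 groups had at most 2 of the 200 brightest probes lowered more than 16-fold. A weaker hybridisation or another amount of spike-in stays open only for the low spike-in signals. Their mean log2 was 8.89 and 8.31, the latter the lowest of the 120. That mean lay 0.39 and 1.35 above the array's 75th percentile, against a median of 2.255 and a range of 0.87 to 3.33 on the other arrays. For the lowered bright probes, the 31350 and 29876 probes that stayed well above background argue against a weaker hybridisation as the source. It also stays open that both arrays may carry RNA of another kind than the labelled liver samples, since 71 of the 200 brightest probes were lowered more than 16-fold on both, with a median log2 deviation from the median array of -11.59 and -10.71 over those probes, and their deviations correlated with each other at r = 0.855 across probes. Both arrays sat on 1 slide, whose other two arrays correlated with the median array at 0.978 and 0.98, and which RNA they carried was not tested.

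The same arrays set single values of named probes. In crab hepatopancreas at 14 d, replicate 2 measured 5.45 at C043R091 (others -0.61 to 0.16), -6.89 at C027R095 (others 0.50 to 3.68) and -6.29 at C105R095 (others 2.97 to 4.49). In herring tails at 14 d, replicate 2 measured -3.30 at C228R017 (others 5.92 to 6.76), -1.54 at C013R095 (others 2.24 to 3.15) and 0.52 at C080R059 (others -5.30 to -3.85).

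The diet effect differed between 14 d and 56 d at 127 probes over the 9 diets, led by C172R046 and C262R013 (adjusted p = 4.88e-04 for each, limma). For herring tails it differed at 343 probes, with C013R095 at 3.01 and C093R164 at 2.79 on the log2 scale. C080R059 and C155R007 had fitted differences of -3.72 and -3.67, but most of their arrays were not well above background and no bound could be set, so these are no measured sizes. Over the alternatives they ran from -4.14 to -0.28 and from -4.06 to -0.53, and replicate 2 of herring tails at 14 d, 1 of the 2 unlike arrays, held the highest value of each probe in its group. Of 100 random splits, 3 gave as many probes as the 343 for herring tails, the real one included, and the highest of the others gave 3394.

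The response to herring tails at 14 d, absent from the calls at 56 d, was weighed against technical sources. The 2 unlike arrays do not account for all of it, since 756 of the 1153 original calls also passed without them, among 1149. The near-equal counts cannot show that these arrays played no part, because the shared spread then no longer held theirs. Sea cucumber at 14 d, which holds neither array, went from 259 to 712 in the same way. Slide does not account for all of the herring tails response. With slide as a fixed block 599 probes passed, and at most 307 in the other random splits fitted with that block. Nor does array brightness, since 1367 passed with it as a covariate and at most 358 in the other splits fitted so. Open explanations are the diet itself, and differences in tank, sampling or RNA handling that the labels do not give and that were not tested. The response may be a short-lived effect of the diet, a hypothesis found and tested on the same arrays.

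Other single arrays stood apart as follows. C024R016 measured -1.46 in crab hepatopancreas replicate 5 at 14 d (others -3.01 to -2.44). C201R032 measured 5.82 in control replicate 3 at 14 d (others 6.86 to 7.34). C104R118 measured 0.45 in control replicate 2 at 56 d (others 1.25 to 1.59) and 1.29 in shrimp hydrolysate B replicate 6 at 56 d (others -0.84 to -0.22). C030R114 measured 0.0948 in herring milt replicate 3 at 56 d (others -2.30 to -1.69). In shrimp fine meat at 56 d, C102R161 measured 1.10 in replicate 2 (others 0.14 to 0.40) and C199R155 measured 2.75 in replicate 5 (others 1.32 to 1.85). C155R007 measured -4.32 in herring tails replicate 5 at 56 d (others -5.40 to -5.17). The correlation with the median array was 0.944 in herring milt hydrolysate replicate 3 at 56 d (others 0.971 to 0.98). The number of probes well above background was 18803 in herring tails replicate 4 at 14 d (others 29876 to 33756), 22265 in herring milt hydrolysate replicate 4 at 56 d (others 27340 to 29926) and 24511 in shrimp hydrolysate C replicate 3 at 14 d (others 28751 to 31131).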

How the results depend on the processing

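Scan day, array brightness, the arrays left out for few probes, the 2 unlike arrays and single arrays were alternatives chosen after seeing the data, and the others were planned. The planned gene-list alternatives (camera with an estimated correlation, and the mean of a gene's probes) were not run, because no probe has a gene name. Unless another cause is named, the cause of a change was not tested. Depth here is signal over background, and it limits the dim probes most, such as C080R059 and C155R007, which were well above background on no array of 1 of their groups.

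With the replicate number as a block (a paired fit), all 38 counts stayed within 1.5-fold, with 1257 for herring tails, 280 for sea cucumber and 95 for crab hepatopancreas at 14 d, and 3567 for the days, and all 48 named calls were kept. Deviations of arrays with the same replicate number correlated at a mean r of 0.0153 across probes, so the numbers were not treated as pairs. No named probe reversed its direction under any alternative. Of the 48 named calls 18 were kept with slide as a fixed block, 20 with normexp, 38 with slide as a random block, 40 with quantile normalization, 40 with scan day, 41 with array brightness, 44 with no filter, 46 without the 3 arrays with fewest probes above background and 47 without the 2 unlike arrays. With the authors' values 33 of the 42 that could be compared were kept, and with only the arrays compared 12 of 42. Over the alternatives, leave-one-out included, the calls kept least often were C091R025 with herring milt hydrolysate (7 of 24), C104R118 and C140R147 with shrimp hydrolysate B (9 of 24 each), C093R164 in herring tails between the days (9 of 25), C262R013 (11 of 24) and C007R057 (11 of 23) with herring roe, and C030R114 in milt hydrolysate against milt (11 of 24).

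Quantile normalization gave 1 for herring roe, 3 for shrimp hydrolysate B, 59 for herring milt hydrolysate against milt and 5 for shrimp hydrolysates against fine meat at 56 d, and the other 34 of 38 counts stayed within 1.5-fold. Without the filter on dim probes, milt hydrolysate against milt at 56 d gave 21.

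Normexp gave 445 for the diet effect at 14 d, 66 at 56 d, 21 for the interaction, 166 for herring tails and 9 for sea cucumber at 14 d, and 1321 for the days. At 56 d it gave 0 for herring milt, 1 for herring roe, 1 for herring milt hydrolysate, 0 for shrimp hydrolysate B, 0 for shrimp hydrolysate C, 0 for milt hydrolysate against milt and 0 for shrimp hydrolysates against fine meat. Of the scalings compared (normexp, quantile normalization and the authors' values), only normexp shifted the median of all probes by more than 0.1 on the log2 scale, for example by 0.34 for sea cucumber and -0.23 for crab hepatopancreas at 14 d and 0.47 for shrimp hydrolysate C at 56 d.

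The authors' values gave 196 for the interaction, 127 for crab hepatopancreas at 14 d, and at 56 d 27 for sea cucumber, 20 for shrimp hydrolysate B, 65 for milt hydrolysate against milt, 3 for shrimp hydrolysate C against B and 0 for shrimp hydrolysates against fine meat. At 14 d they gave 1 for shrimp hydrolysate C against B and 1 for shrimp hydrolysates against fine meat. Between the days they gave 9 for sea cucumber, 1 for herring milt and 1 for shrimp hydrolysate B, where the model of the 75th percentile values gave 0. The share of rises moved by more than 10 points under some scalings. For herring tails at 14 d 39.2% of calls were rises, and 59.6% with normexp. For sea cucumber at 14 d the share was 36.7%, and 52.1% with the authors' values, and at 56 d 72.7% and 55.6%. For milt hydrolysate against milt it was 35.3%, against 18.6% with quantile normalization and 13.8% with the authors' values. For crab hepatopancreas at 14 d it was 72.9%, and 83.3% with normexp. For herring tails between the days it was 65.0%, against 79.2% with quantile normalization and 76.7% with the authors' values.

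With slide as a fixed block the calls of comparisons with at least 10 of them all kept their direction, at a median of 0.656 to 0.966 of their size, though they were chosen on the same arrays. With normexp they were at 0.394 to 0.798, and not all kept their direction. The share that did was 84% for herring tails between the days, 89.2% for sea cucumber and 90% for crab hepatopancreas at 14 d, and 91.1% for the days. In the other such comparisons it was 99.9% or more. Slide as a fixed block gave 109 for the diet effect at 56 d, and at 14 d 10 for crab hepatopancreas, 599 for herring tails, 1 for shrimp fine meat, 67 for sea cucumber and 2 for shrimp hydrolysate C against B. At 56 d it gave 3 for herring milt, 3 for sea cucumber, 0 for herring roe, 0 for herring milt hydrolysate, 2 for shrimp hydrolysate B, 1 for shrimp hydrolysate C, 0 for milt hydrolysate against milt and 0 for shrimp hydrolysates against fine meat, and it gave 4 for the days on the control diet, and between the days 32 for herring tails and 3 for herring roe. Slide as a random block, with a consensus correlation of 0.307, gave 195 for the interaction, 175 for crab hepatopancreas at 14 d, and at 56 d 2 for herring milt, 6 for shrimp hydrolysate C, 18 for milt hydrolysate against milt and 0 for shrimp hydrolysates against fine meat, and 8 for the days on the control diet. Scan day gave 234 for the interaction, 565 for sea cucumber at 14 d, and at 56 d 1 for herring roe, 2 for herring milt hydrolysate, 11 for shrimp hydrolysate B, 186 for milt hydrolysate against milt and 0 for shrimp hydrolysates against fine meat, and 1 for the days on the control diet.

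Array brightness gave 292 for the diet effect at 56 d, 79 for the interaction, 116 for crab hepatopancreas and 146 for sea cucumber at 14 d, and at 56 d 1 for herring milt hydrolysate, 55 for milt hydrolysate against milt and 0 for shrimp hydrolysates against fine meat. Without the 3 arrays with fewest probes above background, the interaction gave 36, herring roe at 56 d gave 5 and herring tails between the days gave 165.

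Without the 2 unlike arrays the spread between arrays shared by all groups no longer holds theirs. The diet effect at 56 d then gave 1815, the interaction 474, sea cucumber 712 at 14 d and 40 at 56 d, and at 56 d shrimp hydrolysate B gave 109, milt hydrolysate against milt 230, shrimp hydrolysate C against B 10, shrimp hydrolysates against fine meat 9, and the days on the control diet gave 5. A model of only the arrays compared, with fewer arrays behind its spread, gave 989 for the diet effect at 14 d, and at 14 d 0 for crab hepatopancreas, 5 for herring tails, 513 for sea cucumber and 1 for shrimp hydrolysates against fine meat. At 56 d it gave 0 for herring milt, 1 for sea cucumber, 0 for herring roe, 2 for herring milt hydrolysate, 132 for shrimp hydrolysate B, 1 for shrimp hydrolysate C, 0 for milt hydrolysate against milt and 0 for shrimp hydrolysates against fine meat. Leaving the 2 unlike arrays out of such a model gave 115 for crab hepatopancreas and 541 for herring tails.

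Leaving out 1 replicate number or 1 array at a time gave 1114 to 2225 for the diet effect at 14 d, 136 to 767 at 56 d, and 12 to 292 for the interaction. At 14 d it gave 0 to 287 for crab hepatopancreas, 616 to 2306 for herring tails, 30 to 587 for sea cucumber, 0 to 1 for herring milt, 0 to 4 for herring roe, and 0 to 1 for each shrimp hydrolysate. At 56 d it gave 0 to 7 for herring milt, 2 to 34 for sea cucumber, 0 to 4 for herring roe, 0 to 10 for herring milt hydrolysate, 2 to 22 for shrimp hydrolysate B and 1 to 4 for shrimp hydrolysate C. It gave 0 to 208 for milt hydrolysate against milt, 0 to 14 for shrimp hydrolysate C against B and 0 to 11 for shrimp hydrolysates against fine meat at 56 d. For the days it gave 2306 to 3939 over all diets and 0 to 11 on the control diet, and for herring tails between the days 23 to 720.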

Other observations

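The tests of explanations in this part were chosen after the results were seen. A few probes took separate high and low levels in single arrays regardless of diet. Over the 118 arrays other than the unlike pair, C237R146 was high on 95 arrays, at 6.87 ± 0.60 (SD), and low on 23, of which 21 were not well above background. C145R009 was high on 96 arrays, at 5.57 ± 0.70 (SD), and low on 22, of which 20 were not well above background. With dim values raised to their array's background limit, no array lay in a gap of at least 7.75 on the log2 scale for C237R146 and 5.78 for C145R009. Only 2 arrays were low on both probes and 43 on either. Of 34129 probes looked at, 10 had a gap of more than 4-fold and 30 one of more than 2-fold.

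Slide cannot account for these levels, since 19 slides held arrays of both levels for C237R146 and 16 for C145R009, and diet and day cannot, since 15 of the 20 groups held both levels for each probe. Low arrays fell together on slides no more often than in permutations of the labels (one-sided permutation p = 0.931 and 0.5), and in groups likewise (one-sided permutation p = 0.639 and 0.806). Low arrays were 12 of 14 d and 11 of 56 d for C237R146 (two-sided Fisher's exact p = 0.818), and 10 and 12 for C145R009 (p = 0.814, Fisher's exact). The levels may reflect differences between individual fish, such as a gene or a transcript that some carry and others lack, but no genotype was measured and this was not tested.

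The profiles of the 9 diets against the control diet correlated with each other across probes, at a mean r of 0.407 over 36 pairs at 14 d and 0.406 at 56 d. Probes are not independent replicates, and every pair shared the same 6 control arrays. Simulated groups drawn around the mean of all groups of the day and set against the real controls gave 0.461 and 0.494. That mean holds any response common to the diets, so this simulation cannot tell such a response from the shared controls. With the control arrays split so that no pair shared any, the mean r was 0.104 and 0.00861. The mean covariance was then 0.0287 at 14 d and -0.00218 at 56 d, against 0.0787 and 0.0706 with shared controls. Likeness of this size at 56 d therefore needs no shared response. At 14 d part of it remained, and its cause was not tested.

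The first principal component of all arrays held 18.1% of the variance, and slide accounted for 86.2% of that component. Deviations from the group means correlated at a mean r of 0.206 between arrays on the same slide. Across all 7140 pairs of arrays the highest correlation was 0.984, and 0 pairs were identical.

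Random splits of the same arrays, 100 per result with the real one among them, seldom reached the real count for most results with calls. Each result was judged by itself, with no correction for the number of results. The splits regrouped arrays regardless of slide, although arrays on a slide were alike, so they do not exclude slide. With slide as a fixed block crab hepatopancreas at 14 d had 10 calls, with the original calls all in the same direction at a median of 0.907 of their size, and at 56 d herring roe and herring milt hydrolysate had 0, with C104R118 at -1.56 and -1.69 against -1.62 and -1.60 without the block. For the following only the real split gave as many probes. The real count and the highest other were 1153 and 459 for herring tails, 259 and 4 for sea cucumber and 70 and 48 for crab hepatopancreas at 14 d. At 56 d they were 545 and 9 for the diet effect, 11 and 1 for sea cucumber, 3 and 0 for herring roe, 4 and 1 for herring milt hydrolysate and 7 and 2 for shrimp hydrolysate B. They were 127 and 1 for the interaction and 3498 and 52 for the days. For milt hydrolysate against milt at 56 d 4 splits reached the 34 probes, and the highest other gave 329.

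For other results more of the splits reached the real count, and chance was not excluded. For the diet effect at 14 d 7 splits reached the 2009 probes, with a highest other of 3877, while without the 2 unlike arrays 1 split, the real one, reached 2629, with a highest other of 2005. At 56 d 15 splits reached the 1 probe of herring milt (highest other 206), 9 reached the 3 probes of shrimp hydrolysate C (highest other 9173) and 7 reached the 2 probes of shrimp hydrolysates against fine meat (highest other 8760). Slide accounted for 86.2% of the first component of all arrays. Over their own arrays, the splits with 206, 9173 and 8760 probes accounted for 59.8%, 62.0% and 63.3% of that component. The real groups accounted for 0.343%, 0.696% and 15.3%, so these 3 splits point to a structure of the arrays that largely follows slide. The split with 3877 probes did not, at 17.7% against 19.7% for the real groups. Nor did the highest split for herring tails between the days, with 3394 probes, at 24.4% against 27.2%. The real groups of sea cucumber and herring tails at 14 d accounted for 50.7% and 35.2% of the first component, so part of their calls may follow this structure of the arrays. With slide as a fixed block 67 and 599 probes passed, and all original calls kept their direction, at a median of 0.89 and 0.81 of their size. Those calls were chosen on the same arrays, so their direction does not settle this, and no slide held both sea cucumber and control. For a comparison with a count of 0 the splits test nothing, since all 100 must give at least 0 probes. Among these the highest other split gave 751 for shrimp hydrolysate C against B at 56 d, 96 for shrimp hydrolysates against fine meat and 49 for shrimp hydrolysate B at 14 d, and 5571 for the change of shrimp hydrolysate C between the days, and 26 or fewer for the rest.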
